A study of Mus musculus with 202 samples.

How the data were processed

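RNA of single mouse oocytes at metaphase II (MII), the arrest at which an egg is ready for fertilisation, was measured with Smart-seq2. Smart-seq2, named in the labels, is a full-length method for single cells without unique molecular identifiers. The 202 libraries, each 1 oocyte, fell into 11 groups by generation (F1, F2 or F3) and by the treatment of the founding F0 female. She had received a control diet (CD) or a diet high in fat and sugar (HFHS), with vehicle (Veh) or dihydrotestosterone (DHT), an androgen. Groups were taken from the sample titles. The characteristics of 36 samples contradicted their titles: 15 titled F1 HFHS+Veh and 5 titled F2 HFHS+DHT named the other hormone treatment. Another 8 titled F2 HFHS+Veh (all 5 of animal 10 and 3 of animal 5) named F3, and 8 titled F3 HFHS+Veh (animal 22) named F2. The number before the point in the titles of F2 CD+Veh, CD+DHT and HFHS+Veh and of F3 HFHS+Veh oocytes was taken as the animal, an inference from the titles. The other groups named no animal.

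The authors deposited a table of raw counts per gene symbol with 24582 lines, of which 92 were ERCC spike-in RNAs and 1 was eGFP, with 0 counts. The other 24489 lines held 23997 symbols, 492 repeated lines having been summed. STAR 2.4.2a, Seurat 2.0 and the mm10 build are named in the submitters' processing notes. The counting program, the gene annotation and the use of strand are not given in the sources used here. Genes that share reads with near-identical copies are therefore uncertain, such as ribosomal proteins, olfactory receptors and the Hsd3b, Akr1c and Nlrp families. So are genes overlapping another transcript on the opposite strand (Gnas, Timp1). The authors also deposited an RPKM table (reads scaled to gene length and library total) of the same libraries, with gene lengths not given in the sources used here. The authors' normalised tables held natural log values of counts scaled to 10000 per oocyte plus 1. The 2 such tables used, with 15758 and 16239 genes, covered 137 oocytes, 134 of them among those kept here. They departed from the count table by a relative 1.60e-13 at most. A further normalised table was not used, because its last line was cut short. In the counts, 27 symbols had been turned into dates and 88 held merged names; these were not named. No mitochondrially encoded gene had a line in the count table, so that list gave no value (0 lines). Gene positions are those of GENCODE vM21 on GRCm38, the assembly that mm10 denotes; 22643 symbols matched it.

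Oocytes with at least 100000 gene counts and at least 4000 genes with a count were kept: 157 of 202, with 45 left out. Spike-ins took a median 0.252% of the counts of the kept libraries (0.0280% to 14.33%) and were left out of library sizes. No 2 libraries were identical (0 pairs). The smallest chi-square per degree of freedom between 2 libraries of a group was 2.45, so none was treated as a repeat of another. The range of counts of each group is given in the report. PCR copies are not independent molecules and there were no molecular identifiers, so all intervals and floors cover counting error only.

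For F2, counts were summed over the oocytes of each animal, and CD+Veh (animals 2, 3, 13 and 14), CD+DHT (6, 7, 8, 9 and 17) and HFHS+Veh (4, 5, 10 and 19) entered 1 edgeR 4.0.16 quasi-likelihood fit in R 4.3.3. Scaling was by TMM and genes were kept by filterByExpr, with a Benjamini-Hochberg adjusted p under 0.05 as the threshold. F2 HFHS+DHT named no animal and held 5 oocytes, all with a contradictory hormone label, so it entered no comparison. Gene lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with adjustment over the lists, and with fry. For F1 and F3 no animal was named in at least 1 of the groups compared, so each group was 1 sample of cells and no test was made. Counts were pooled over the kept oocytes, scaled to a total of 1e6 (CPM) and given with exact Poisson 95% intervals. The median log2 fold of each list with at least 5 members at a mean of at least 5 CPM was placed among the medians of 10000 random lists matched on expression in 20 bins. It was called outside where it lay below the 2.5th or above the 97.5th percentile. By that construction 5% of unrelated lists lie outside if their members vary independently. Random members were drawn one by one, so a list whose members vary together lies outside more often. In F2 HFHS+Veh camera estimated correlations of 0.185 for oxidative phosphorylation, 0.440 for ribosomal proteins and 0.407 for cumulus markers. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used.

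The named genes followed a rule. For F2 it took the largest changes past the threshold with a mean of at least 10 CPM. As fewer than 5 passed in each direction, the 5 genes with the smallest p in each direction are named and said not to pass. For F1 and F3 it took the 10 largest folds in each direction. The gene had to reach a pooled 20 CPM in either group and a count in at least 80% of the oocytes of the higher group. The fold of the oocyte medians, each plus 1 CPM, had to be at least 2 the same way. For a list outside, the 4 members with the largest fold in its direction among those with a pooled 20 CPM in either group were added, so members at lower levels with larger folds are not named. For F3 HFHS+Veh the direction had to be the same in the animals with kept oocytes, 22 and 26, since animal 25 had none. Symbols beginning Gm with digits, ending in Rik or -ps were passed over for the next gene. These were 1 higher in F1 HFHS+Veh, 1 lower in F1 HFHS+DHT, 1 lower in F3 CD+DHT and 2 lower in F3 HFHS+Veh. Where a group had 0 counts, folds used a floor of 3 counts over the group. The 20 lists, the rule, the tests and most alternatives were fixed before the data were examined. They covered oocyte functions (maternal effect genes, zona pellucida and secreted factors, meiotic spindle, mRNA storage, chromatin regulators, imprinted genes, zygotic genome activation). They also covered metabolism and stress (nuclear and mitochondrially encoded oxidative phosphorylation, mitochondrial dynamics, lipid, insulin and glucose, androgen and steroid, unfolded protein response, oxidative stress, DNA damage, ribosomal proteins). The rest were genes near polycystic ovary syndrome loci and markers of cumulus and granulosa cells and of blood, immune and stromal cells.

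Alternatives recomputed for F2 were DESeq2 1.42.0 size factors and its Wald test, no filter on genes, limma on the mean log2(CPM + 1) of each animal's oocytes and limma voom with the animal as a random block. Further ones were only the groups compared, oocytes with contradictory labels left out, each animal left out and camera with an estimated correlation. Oocytes were also taken without a filter or with a stricter one (300000 counts and 8000 genes). For F1 and F3, pooled values were replaced by means or medians of oocyte CPM, TMM scaling or the authors' RPKM, and minimum levels of 1 and 20 CPM were used. Chosen after seeing the data were only the oocytes in the 2 normalised tables used, the animal number as a linear term and single oocytes left out (each in turn for F1 and F3). So was leaving out 4 oocytes above a fence for cumulus cell markers. The fence, 2031 CPM, was set at the upper quartile plus 1.5 interquartile ranges of the summed marker level on a log2 scale. The F2 test was tested on simulated data from the real means and library sizes with 200 changed genes. The changed genes were drawn from those with a mean of at least 10 CPM on a log2 scale, and genes were simulated independently. Recovery of genes at lower levels was not simulated. For CD+DHT it recovered 27.8% of 100 genes changed 2-fold and 94.6% of 100 changed 4-fold, with a mean of 5 false calls over 5 runs. For HFHS+Veh it recovered 24.8% and 87.8%, with 4.6 false calls. In a simulated F1 comparison a list with 40 members raised 2-fold reached percentile 100 and 0 of 18 other lists lay outside. That simulation drew each gene independently with counting error only, so it could not show the effect of members that vary together.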

Results

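The study followed oocytes of C57Bl/6J mice over 3 generations descending from F0 females. These differed in diet (CD or HFHS) and in hormone treatment (Veh or DHT), and the title names prenatal androgen exposure and susceptibility to polycystic ovary syndrome. Each library was 1 MII oocyte. Gene counts per library ran from 615 to 16359078 over all 202 libraries. In F1, 10 of 15 CD+Veh oocytes were kept (158259 to 7660532 counts) and 8 of 15 CD+DHT (185620 to 3275603). So were 14 of 15 HFHS+Veh (511862 to 10481507) and 13 of 15 HFHS+DHT (133654 to 4070350). In F2, 16 of 20 CD+Veh oocytes of 4 animals were kept (220777 to 13381587), 25 of 25 CD+DHT of 5 animals (348855 to 13378950) and 20 of 20 HFHS+Veh of 4 animals (424872 to 11938267). F2 HFHS+DHT, with 5 of 5 kept (1728447 to 7156586), entered no comparison. In F3, 20 of 24 CD+Veh oocytes were kept (309794 to 6892284), 13 of 24 CD+DHT (205518 to 16359078) and 13 of 24 HFHS+Veh (186934 to 1186699). The last comprised 5 from animal 22, 8 from animal 26 and 0 from animal 25. The largest library held 41.5% of the pooled counts of F1 CD+DHT, 34.7% of F1 CD+Veh and 34.2% of F3 CD+DHT. Values in square brackets are exact Poisson 95% intervals of pooled counts and cover counting error only.

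Transcripts of cumulus and granulosa cells, the somatic cells that surround the oocyte, were present at differing levels. The summed level of 34 markers had a median of 252 CPM over the kept oocytes. Pooled over each group it was 239 CPM in F1 CD+Veh, 220.4 in F1 CD+DHT, 602 in F1 HFHS+Veh and 404 in F1 HFHS+DHT. In F3 it was 594 in CD+Veh, 367 in CD+DHT and 463 in HFHS+Veh. Oocytes above the fence of 2031 CPM were F1 HFHS+Veh oocyte 1 (2234 CPM), F2 HFHS+Veh oocyte 1 of animal 5 (2197 CPM), F3 CD+Veh oocyte 19 (3189 CPM) and F3 CD+Veh oocyte 21 (25372 CPM, with 14.33% spike-in counts and 4603 genes). They stayed in the comparisons, although F3 CD+Veh oocytes 19 and 21 were not among the 18 of that group in the 2 normalised tables used.

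**Figure D1:**
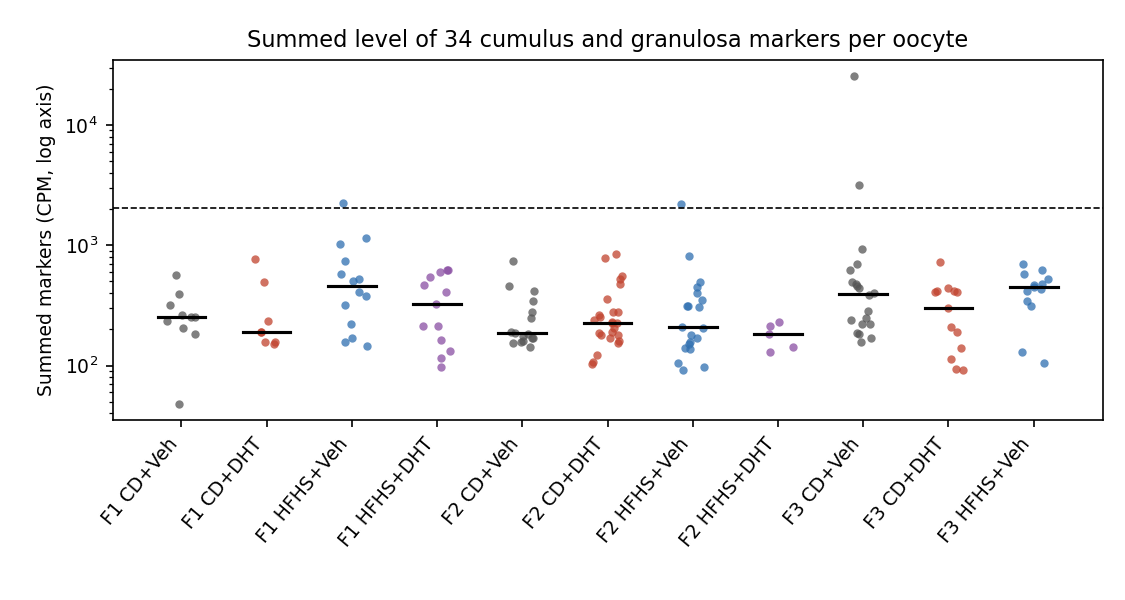
Summed level of 34 cumulus and granulosa cell markers in each kept oocyte, on a log axis in CPM, by group. Points are oocytes, black bars are group medians and the dashed line is the fence of 2031 CPM, which 4 oocytes exceed, F3 CD+Veh oocyte 21 by the widest margin at 25372 CPM.

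The F1 comparison of CD+DHT with CD+Veh asked how oocytes of daughters of DHT-treated females differed from controls on the same diet. Highest relative to controls by the naming rule was Cobl, an actin nucleator, at 39.6 CPM [35.3 to 44.3] against 11.9 CPM [10.47 to 13.39] (log2 fold 1.74; chromosome 11, 12236608 to 12464960). It was followed by Insm1, a zinc finger transcription factor, at 42.1 CPM [37.7 to 46.9] against 15.8 CPM [14.19 to 17.6] (log2 fold 1.42; chromosome 2, 146221921 to 146225020). Lowest by that rule was Gadd45gip1, a protein of the mitochondrial ribosome, at 12.4 CPM [10.07 to 15.1] against 31.9 CPM [29.6 to 34.3] (log2 fold -1.36; chromosome 8, 84831522 to 84835482). Then came the mitochondrial protein Nipsnap1 (8.35 against 20.7 CPM) and Prim1, the catalytic subunit of DNA primase (10.13 against 24.6 CPM; chromosome 10, 128015168 to 128030037). Of the 18 gene lists, 1 lay outside the range of random lists. Chance alone gives about that many by the rule used, so this count is no evidence of a change. The list was DNA damage response and apoptosis, with 24 of 31 members lower, a median log2 fold of -0.17 and percentile 1.26. Its members included Brca1, needed for repair of double-strand breaks (77.6 CPM [71.6 to 83.98] against 104 CPM [99.99 to 109]; log2 fold -0.43; chromosome 11, 101488764 to 101551955). Others were Apaf1, the core of the apoptosome (-0.28), the antiapoptotic Bcl2l1 (-0.26) and Casp8, an initiator caspase (-0.26).

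Other genes higher in F1 CD+DHT were Uqcr11, a subunit of respiratory complex III (log2 fold 1.35), the heterochromatin protein Bahd1 (1.23), the peptide transporter Slc15a2 (1.17) and Parp8 (0.99). So were the beta-tubulin Tubb5 (0.93), the homeodomain protein Pbx2 (0.82), the corepressor Nab2 (0.81) and Pycrl, of proline synthesis (0.78). Lower were the motor Myo1d (-1.28), the interleukin subunit Il23a (-1.25) and Sap130 of the Sin3 corepressor complex (-1.22). So were the nuclear receptor corepressor Lcor (-1.19), the protein repair enzyme Pcmt1 (-1.15), Samd7 (-1.02) and Muc20 (-1.01). Log2 folds of the named genes ran from -1.36 to 1.74. The yardstick for them is the spread between F2 animals, where the SD of log2 CPM had a median of 0.66 over genes and was 1.74 for Cobl and 0.66 for Insm1. The other 17 lists had medians from -0.20 to 0.20 and percentiles from 9.62 to 97.4. With no animal named for F1, each group was 1 sample and nothing was tested. Kept CD+DHT oocytes had a median of 8398 genes and 434905.5 counts, against 9643.5 genes and 935112.5 counts in controls. Library quality was not parted from treatment. The DNA damage list came inside the range of random lists without control oocyte 1, 6 (median -0.07) or 11, with oocyte medians (percentile 6.03), the stricter oocyte filter (4.29) or a minimum of 1 CPM (3.43). Uqcr11 had a log2 fold of 0.73 without CD+DHT oocyte 2, and Pycrl 1.57 without control oocyte 6. Bcl2l1 turned to 0.10 without CD+DHT oocyte 6, to 0.05 without control oocyte 6 and to 0.38 with oocyte medians.

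The F1 comparison of HFHS+Veh with CD+Veh asked about the maternal diet alone, although the characteristics of all 15 oocytes titled HFHS+Veh named dihydrotestosterone. Its controls were those of F1 CD+DHT, which links Prim1, Samd7 and Sap130, lower in both. Highest by the naming rule was Spp1, the secreted phosphoprotein osteopontin, at 1183 CPM [1173 to 1193] against 52.9 CPM [49.9 to 56.0] (log2 fold 4.48; chromosome 5, 104435118 to 104441050). Beside it were Hsd3b1, which makes progesterone, at 81.9 CPM [79.2 to 84.7] against 4.35 CPM [3.52 to 5.31] (4.24; chromosome 3, 98852194 to 98859794), and Akr1c18, which breaks it down, at 147 CPM [143 to 151] against 8.42 CPM [7.26 to 9.72] (4.12; chromosome 13, 4132615 to 4150654). Members of a list entered at a mean of 5 CPM over both groups, so some cumulus markers entered only through high HFHS+Veh levels. That favours a large median, and against the same controls 8 of these markers were measured in F1 CD+DHT. Summed over 34 markers, oocyte medians were 458 CPM in HFHS+Veh and 255 CPM in CD+Veh. The cumulus and granulosa marker list had a median log2 fold of 2.56, percentile 100, with 10 of 14 members higher. Among them were the protease inhibitor Timp1 (24.7 against 0.860 CPM; chromosome X, 20870166 to 20874735), Tnfaip6, which crosslinks the hyaluronan matrix of the cumulus (48.3 against 2.13 CPM; chromosome 2, 52038009 to 52056686), and the glutathione transferase Mgst1 (78.8 against 7.79 CPM). Nuclear oxidative phosphorylation subunits were also higher (median 0.22, percentile 100, 38 of 55 members), as were ribosomal proteins (0.41, percentile 99.8, 14 of 16) and androgen and steroid genes (0.15, percentile 99.8, 17 of 25). Lowest of the genes named by the rule was Prim1 (11.6 CPM [10.6 to 12.6] against 24.6 CPM [22.61 to 26.796]; -1.09), beside the spindle protein Tacc3 (89.5 against 143 CPM) and Mki67, which coats mitotic chromosomes (97.3 against 149 CPM).

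Further genes higher in F1 HFHS+Veh were the lactate dehydrogenase Ldha (log2 fold 4.05; chromosome 7, 46841475 to 46855627), Skil, a corepressor of SMAD signalling (3.95) and the proteoglycan Sdc4 (3.80). So were the epoxide hydrolase Ephx2 (3.73), the thiol dioxygenase Ado (3.31) and the zinc transporter Slc39a1 (3.29). Lower were the golgin Golga3 (-0.87), Dbndd1 (-0.87), Samd7 (-0.76), Rnf32 (-0.73), Sap130 (-0.65), Csmd3 (-0.64) and Erich5 (-0.60). Respiratory subunits with the largest folds among members of at least 20 CPM were Cox4i1 (20.99 CPM [19.6 to 22.41] against 6.84 CPM [5.79 to 8.02]; chromosome 8, 120668222 to 120674207), Ndufa2 (0.90), Uqcr10 (0.81) and Cox6b1 (0.69). The ribosomal examples were Rps14 (0.83), Rplp0 (0.55), Rpl4 (0.51) and Rps15a (0.26). Beyond Hsd3b1 and Akr1c18 the steroid list held Hsd17b4 (0.47) and Hsd17b12 (0.42), the latter also an enzyme of fatty acid elongation. Between F2 animals the SD of log2 CPM was 3.27 for Spp1, 3.99 for Hsd3b1 and 3.82 for Akr1c18, beside log2 folds of 4.48, 4.24 and 4.12 here.

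Pooled cumulus marker RNA was 602 CPM in F1 HFHS+Veh against 239 in its controls. Without HFHS+Veh oocyte 1, above the cumulus fence, the cumulus list stayed outside (median 1.85). Oxidative phosphorylation (0.03, percentile 71.0), ribosomal proteins (0.23, 96.4) and steroid genes (0.07, 91.5) came inside. The steroid list also came inside without HFHS+Veh oocyte 2 or 12 or control oocyte 1 or 6, and with equal weights of oocytes (0.06, 87.6) or RPKM (0.06, 88.1). Without HFHS+Veh oocyte 1 the log2 folds were 3.25 for Spp1, 2.26 for Skil, 2.13 for Sdc4, 2.59 for Mgst1, 1.85 for Ado, 1.79 for Slc39a1, 3.84 for Timp1 and 3.56 for Tnfaip6. Without oocyte 2 they were 3.49 for Hsd3b1 and 3.3987 for Akr1c18. Single control oocytes left out moved folds away from 0, so the control levels leaned on them: 6.75 for Hsd3b1 (oocyte 12), 5.52 for Akr1c18 (oocyte 14), 5.45 for Timp1 (oocyte 2), and 6.64 for Tnfaip6, 4.42 for Mgst1 and 3.99 for Slc39a1 (oocyte 11). The control median of Hsd3b1 was 0.079 CPM, against 4.35 pooled. With a minimum of 20 CPM the oxidative phosphorylation median was -0.04 and with oocyte medians that of steroid genes was -0.02. With that minimum the ribosomal list also came inside (percentile 95.3).

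Within HFHS, the F1 comparison of HFHS+DHT with HFHS+Veh asked about the hormone on the rich diet, with the same label conflict on the HFHS+Veh side. The HFHS+Veh oocytes were those of the comparison with CD+Veh, so a high level in them reads as higher there and lower here. Oxidative phosphorylation (median log2 fold of 0.22 there) and Cox4i1 (1.62 there) were such cases. So were Ldha (4.05 there), Aldoa (2.195) and Pkm (1.60), and also Pcsk5 (2.69), Anxa2 (1.84) and Sgk1 (1.82). A hormone difference was not parted from this. Nuclear oxidative phosphorylation subunits were lower in HFHS+DHT, with 49 of 61 members lower, a median log2 fold of -0.43 and percentile 0. Cox4i1 (8.85 CPM [7.51 to 10.36] against 20.99 CPM [19.6 to 22.41]; log2 fold -1.25), Ndufa8 (-0.85), Cox6b1 (-0.59) and Ndufa13 (-0.51) had the largest folds among its members of at least 20 CPM. Insulin and glucose genes were lower too (median -0.24, percentile 0.635, 30 of 37). They included the glycolytic enzymes Ldha (2.57 CPM [1.87 to 3.44] against 20.2 CPM [18.9 to 21.6]; -2.97), Aldoa (12.8 against 38.2 CPM; -1.57) and Pkm (11.1 against 22.9 CPM; -1.04) and the glucose transporter Slc2a1 (-0.38). Ldha, Aldoa, Pkm, Pcsk5, Anxa2 and Sgk1, all lower, were also in a profile of F3 CD+Veh oocyte 21, the richest in cumulus markers. It held the 100 genes most in excess there among those with a mean of at least 5 CPM over F1 HFHS+Veh and CD+Veh. That choice favours genes high in HFHS+Veh, so their median of -0.67 here can be partly built in. Among the most abundant genes, Wtap, a subunit of the RNA m6A methyltransferase, stood at 10518 CPM [10470.0 to 10566] against 6364 CPM [6340.1 to 6388] (log2 fold 0.72; chromosome 17, 12966796 to 12994169). Wtap also varied widely between F2 animals without following their groups.

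Maternal effect genes, whose products the embryo needs from the egg, had a median of -0.11 (percentile 1.73, 26 of 35 lower) in F1 HFHS+DHT against HFHS+Veh. Examples were the heat shock factor Hsf1 (-0.42), the oocyte transcription factor Lhx8 (-0.29), and Padi6 (-0.28) and Nlrp5 (-0.26) of the subcortical maternal complex. Orthologues of genes near polycystic ovary syndrome loci had a median of 0.23 (percentile 99.7, 10 of 16 higher). Examples were the chromatin protein Hmga2 (0.43), Arl14ep (0.41), the Hippo pathway coactivator Yap1 (326 against 250.1 CPM) and the transcription factor Gata4 (0.32; -0.09 with oocyte medians). By the naming rule the largest folds upward were the calpain inhibitor Cast (21.6 CPM [19.52 to 23.9] against 10.6 CPM [9.65 to 11.6]; 1.03), the vitamin K reductase Vkorc1l1 (1.02), Tma16 (0.9989), Tmem87a (0.99) and Zfp345 (0.86). Next were the membrane mucin Pdpn (251 against 140.2 CPM; chromosome 4, 143267431 to 143299564), the semaphorin Sema4b (0.80), Cdc73 of the Paf1 complex (0.74) and Wrnip1 (0.70). Downward, after Ldha and beside Aldoa, they were Nipsnap1 (5.54 CPM [4.49 to 6.76] against 20.3 CPM [19.01 to 21.7]; -1.88), the proprotein convertase Pcsk5 (-1.73), Gdpgp1 (-1.55) and Cdk5rap1 (-1.54). Next were Btbd9 (-1.46), the membrane-binding Anxa2 (-1.38), the kinase Sgk1 (-1.36) and the arginine methyltransferase Prmt5 (-1.36).

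Kept F1 HFHS+DHT oocytes had a median of 8226 genes and 743276 counts, against 10641.5 genes and 1889952.5 counts in HFHS+Veh. Oocyte medians of Wtap (14070 against 5654 CPM), Paip1 (16150 against 6975), Jag1 (8005 against 4255) and Insig1 (4033 against 1761) were higher. These genes lay at the positive end of the first principal component of F2 animals, where animals had fewer genes detected, and the maternal effect and insulin lists lay toward its negative end (percentiles 0.59 and 1.88). Library quality was not parted from treatment. Pooled cumulus marker RNA was 404 CPM in F1 HFHS+DHT against 602 in HFHS+Veh. Without HFHS+Veh oocyte 1 the oxidative phosphorylation median was -0.24 (percentile 0.80). That list lay outside whichever of the 27 oocytes was left out, but came inside with a minimum of 20 CPM (median -0.07, percentile 25.62) or oocyte medians (2.89). Without HFHS+DHT oocyte 10 the log2 folds were -3.56 for Ldha and -2.05 for Btbd9. The insulin list came inside without HFHS+DHT oocyte 6 (-0.13) or HFHS+Veh oocyte 12 or 14, and the polycystic ovary syndrome list without HFHS+DHT oocyte 6 (0.09). The maternal effect list came inside without HFHS+DHT oocyte 2, 3, 6, 12 or 15 or HFHS+Veh oocyte 6, 11 (median 0.0037) or 12. With equal weights of oocytes the maternal effect (percentile 6.44) and polycystic ovary syndrome (96.4) lists came inside, and with oocyte medians the insulin list did (27.6). With RPKM these 3 lists came inside (6.80 for maternal effect, 95.8 for polycystic ovary syndrome, 4.01 for insulin). The maternal effect list also did with the stricter oocyte filter (3.995) or a minimum of 20 CPM (3.79).

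In F2 the animals were named, and the comparison of CD+DHT (5 animals) with CD+Veh (4 animals) asked whether oocytes of granddaughters of DHT-treated females differed. The edgeR quasi-likelihood test called 0 of 11963 genes, and the DESeq2 Wald test called 2. By edgeR 220 genes had an unadjusted p under 0.05, where 598 would be expected by chance. A count below chance does not show that the groups were alike. With limma on animal means 663 genes had such a p and with voom 533, and neither called a gene. The genes called by DESeq2 were Gjb6, the gap junction protein connexin 30 (chromosome 14, 57123303 to 57133611), lower in CD+DHT with a DESeq2 adjusted p of 0.0231, and Sfrp4. Sfrp4, a secreted Wnt antagonist (chromosome 13, 19623104 to 19632994), was higher with a DESeq2 adjusted p of 1.03e-05. Gjb6 rested on 1 count in 1 of 5 treated animals against 78 counts in all 4 controls, 112 times lower by pooled counts. The interval of that ratio, 19.6 to 4494, covers counting error of the pooled counts only and not the spread between animals. Sfrp4 rested on 188 counts in 3 treated animals against 0, at least 43.5-fold higher.

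By the rule for named genes, the 5 smallest p-values on each side are given for F2 CD+DHT. None passed, with an edgeR adjusted p of 0.9999 for each. Higher in all 5 treated animals than the control mean were Tmem255a (8.42 ± 1.34 CPM in the controls and 39.5 ± 38.0 CPM in CD+DHT; log2 fold 2.23, SE 0.58, edgeR p = 0.00145; chromosome X, 38196573 to 38252439) and the calcium-dependent copine Cpne1 (76.9 ± 5.26 CPM in the controls and 119 ± 20.4 CPM in CD+DHT; log2 fold 0.62, SE 0.17, edgeR p = 0.00245; chromosome 2, 156071842 to 156111965). So were the ubiquitin ligase adaptor Wsb1 (log2 fold 0.75, SE 0.22), the double-stranded RNA receptor Tlr3 (log2 fold 1.14, SE 0.34, with animal 8 far above the other treated animals) and Sec24d of the secretory coat (log2 fold 0.65, SE 0.21). Lower were Gjb6 (log2 fold -6.18, SE 1.28), Zfp12 (log2 fold -4.59, SE 1.39) and Anks4b (33.0 ± 8.05 CPM in the controls and 15.97 ± 3.399 CPM in CD+DHT; log2 fold -1.05, SE 0.32). So were Gnas, the imprinted stimulatory G protein subunit (188 ± 17.09 CPM in the controls and 122 ± 26.76 CPM in CD+DHT; log2 fold -0.62, SE 0.20, edgeR p = 0.00607; chromosome 2, 174284320 to 174346744), and the formin Fmnl3 (log2 fold -1.04, SE 0.35). Values in parentheses are means ± SD over animals (n = 4 controls and n = 5 treated).

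None of the 19 lists measured in F2 was called for CD+DHT, the smallest adjusted p of camera being 0.470. Oocyte lists had median log2 folds of -0.09 (maternal effect), -0.05 (zona pellucida and secreted factors), 0.02 (meiotic spindle), 0.08 (mRNA storage), -0.01 (chromatin regulators), 0.02 (imprinted) and -0.11 (zygotic activation). Metabolic and stress lists had medians of -0.08 (nuclear oxidative phosphorylation), -0.11 (mitochondrial dynamics), 0.03 (lipid), -0.04 (insulin and glucose), 0.13 (androgen and steroid), -0.02 (unfolded protein response), 0.12 (oxidative stress), -0.0045 (DNA damage) and -0.14 (ribosomal proteins). Genes near polycystic ovary syndrome loci had -0.10, cumulus markers 0.10 and the 6 measured blood, immune and stromal markers -0.37, a list with too few members at the minimum of 5 CPM in F1 and F3. The median of the DNA damage list and its camera direction differed in sign. No gene passed when adjusted over the list alone, in any of these lists. Without CD+DHT animal 9 camera called oxidative phosphorylation lower (median -0.18, adjusted p 0.00124), the only list called in this comparison when an animal was left out. That call used the preset correlation of 0.01 and was not repeated with an estimated one, which with all animals was 0.184 (adjusted p 0.893).

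The F2 comparison of HFHS+Veh (4 animals) with the same controls asked about the diet lineage in the same generation. Nuclear oxidative phosphorylation subunits, the respiratory chain proteins encoded in the nucleus, fell as a group, with 51 of 73 members lower, a median log2 fold of -0.12 and a camera adjusted p of 0.000869. With an estimated correlation the adjusted p was 0.751, and fry gave an adjusted p of 0.896. Its members included Ndufa9 of complex I (4.31 ± 1.64 CPM in the controls and 1.04 ± 0.570 CPM in HFHS+Veh; log2 fold -2.05, SE 0.57, edgeR p = 0.00257; chromosome 6, 126821721 to 126849136) and Uqcr11 of complex III (log2 fold -1.35, SE 0.43). Others were Ndufa4 (301 ± 79.7 CPM in the controls and 194 ± 27.3 CPM in HFHS+Veh; log2 fold -0.63, SE 0.23) and Cox6c (log2 fold -0.52, SE 0.22), and none of these genes passed by edgeR. Of the list, 5 members had an unadjusted p under 0.05 and 0 passed adjusted over the list alone (smallest 0.187). No single gene passed the edgeR test either (0 of 11963, with 118 at an unadjusted p under 0.05). DESeq2 called 1, Sfrp4 (DESeq2 adjusted p 4.12e-06), which had 395 counts in 2 of 4 HFHS+Veh animals and 0 in controls, at least 102.8-fold higher.

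The call on oxidative phosphorylation was lost without control animal 3 (adjusted p 0.0795) or 14 (0.256), without HFHS+Veh animal 4 (0.111; median -0.06) or 10 (0.121; median -0.02), and with limma on animal means (0.0618). Oocyte 1 of HFHS+Veh animal 5 lay above the cumulus fence, and without it the median was -0.24 (adjusted p 2.27e-05). Without that oocyte the medians of ribosomal proteins (-0.09), lipid (-0.06), insulin and glucose (-0.0002) and maternal effect genes (0.0083) turned sign and that of cumulus markers was 0.12, none of them called. Without the whole of animal 5 camera called oxidative phosphorylation (-0.34, 5.01e-09), ribosomal proteins (-0.47, 1.44e-05) and cumulus markers (-1.36, 0.00308) lower. These calls rest on the preset correlation of 0.01, whereas the correlations estimated with all animals were 0.185, 0.440 and 0.407, and they were not repeated with estimated correlations.

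Genes with the smallest p for F2 HFHS+Veh, none passing (edgeR adjusted p of 0.9999 for each), included on the higher side the bombesin-family receptor Nmbr (70 counts in 3 animals against 0, at least 18.2-fold), Sfrp4 and Hsd11b1, which regenerates active glucocorticoid (log2 fold 3.23, SE 1.11). The others were Prkar2b, a regulatory subunit of protein kinase A (log2 fold 0.57, SE 0.20, edgeR p = 0.0109; chromosome 12, 31958476 to 32061296), and the motor Myo1a (75 counts against 3, all in 1 control animal; 19.52-fold, 6.43 to 96.8). On the lower side were the glypican Gpc5 (log2 fold -3.67, SE 1.01), Dio2, which activates thyroid hormone (0 counts against 87 in 3 control animals, at least 37.2-fold lower) and Ndufa9. So were Rilpl2 (2 counts against 122, 78.1-fold lower, 21.2 to 652) and Cntnap3 (log2 fold -2.49, SE 0.76). The ranges for Myo1a and Rilpl2 and the folds given as at least a value come from counts pooled over animals. They cover counting error only and not the spread between animals. Median log2 folds of the other oocyte lists were -0.04 (maternal effect), -0.07 (zona pellucida and secreted factors), 0.03 (meiotic spindle), 0.10 (mRNA storage), 0.05 (chromatin regulators), -0.05 (imprinted) and -0.28 (zygotic activation). Medians of metabolic and stress lists were -0.03 (mitochondrial dynamics), 0.08 (lipid), 0.02 (insulin and glucose), 0.06 (androgen and steroid), -0.02 (unfolded protein response), 0.06 (oxidative stress), 0.03 (DNA damage) and 0.19 (ribosomal proteins). Genes near polycystic ovary syndrome loci had 0.11, cumulus markers 0.28 and blood, immune and stromal markers -0.55. None of these lists was called by camera. For the meiotic, insulin, oxidative stress and ribosomal lists the direction given by camera was down although the median was above 0.

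Both F2 lineages were set against the same controls, so their fold changes are linked by construction. Across 5763 genes with at least 10 CPM the log2 folds correlated at Pearson r = 0.544 and Spearman rho = 0.535, where 20 simulations of unchanged groups against those controls gave a mean r of 0.526 (0.505 to 0.548). The covariance was 0.0319 against 0.0584 simulated, a difference of -0.0265. With the controls split so that each lineage had its own 2 animals, r averaged -0.111 over 6 fits (-0.497 to 0.222). Genes are not independent replicates, and no overlap of edgeR calls could be counted since both lineages had 0.

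F2 animals differed from each other in ways their group did not follow. The first principal component of log2 CPM held 27.98% of the variance and set CD+DHT animals 8 (95.2) and 9 (97.51) and HFHS+Veh animal 10 (84.9) apart from CD+Veh animal 3 (-64.3) and HFHS+Veh animal 5 (-69.9). Wtap ran from 1738 CPM in animal 3 to 33380.0 in animal 9, and Nupr1, a stress-responsive transcription regulator, from 0 in animal 8 to 173 in animal 3. Summed cumulus markers per animal were 299.8 ± 171 CPM (SD, n = 4) in CD+Veh, 288 ± 92.6 (n = 5) in CD+DHT and 354 ± 331 (n = 4) in HFHS+Veh, with two-sided exact permutation p = 0.865 and 0.829 against controls. The median number of genes per oocyte was 10614 ± 1297 in controls, 9445 ± 1716 in CD+DHT (exact permutation p = 0.278) and 10502 ± 1404 in HFHS+Veh (exact permutation p = 0.971). The log2 ratio of gene to spike-in counts was 9.95 ± 0.39, 10.19 ± 0.43 (exact permutation p = 0.421) and 9.84 ± 1.02 (exact permutation p = 0.971). Adjusted over the 6 such exact permutation tests each p was 0.971.

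**Figure D2:**
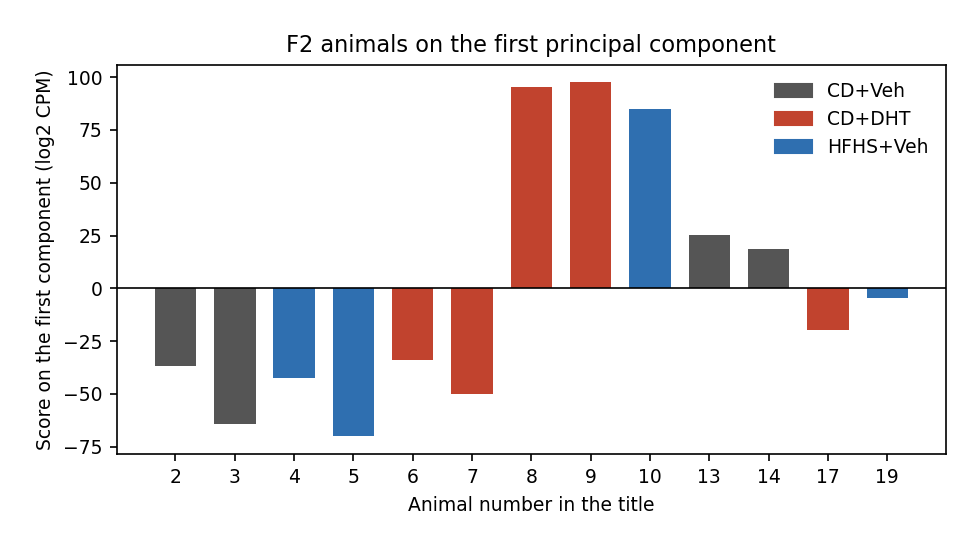
Position of each of the 13 F2 animals on the first principal component of log2 CPM, which holds 27.98% of the variance. Bars are animals coloured by group; animals of each group lie on both sides of 0, from -69.9 for HFHS+Veh animal 5 to 97.51 for CD+DHT animal 9.

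The F3 comparison of CD+DHT with CD+Veh asked whether differences were present in the great-granddaughters of DHT-treated females. By the naming rule, highest relative to controls were the zinc finger gene Zkscan17 (25.29 CPM [23.9 to 26.75] against 2.52 CPM [2.14 to 2.96]; log2 fold 3.32; chromosome 11, 59485520 to 59526751) and the phosphoinositide phosphatase Mtmr3 (24.4 CPM [23.01 to 25.83] against 4.73 CPM [4.19 to 5.31]; 2.37; chromosome 11, 4480868 to 4594863). Next was Mkl1, a coactivator of serum response factor (23.8 against 4.83 CPM). Lowest by the naming rule were Akr1c14, a hydroxysteroid dehydrogenase that reduces dihydrotestosterone (9.67 CPM [8.81 to 10.6] against 93.2 CPM [90.8 to 95.7]; -3.27; chromosome 13, 4049011 to 4090688), and the chondroitin sulfotransferase Chst11 (3.95 CPM [3.404 to 4.55] against 28.3 CPM [26.9 to 29.7]; -2.84; chromosome 10, 82985498 to 83195900). Next was Tmx3, an endoplasmic reticulum oxidoreductase (5.95 against 38.1 CPM). Cumulus markers were lower (median log2 fold -0.65, percentile 0.03, 15 of 17), chromatin regulators had a median of -0.13 (percentile 2.3, 28 of 46 lower) and the unfolded protein response -0.18 (percentile 2.21, 15 of 26 lower).

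Among cumulus markers the matrix proteoglycan Vcan stood at 1.71 CPM [1.36 to 2.13] against 69.6 CPM [67.5 to 71.8] (chromosome 13, 89655312 to 89742509). The gap junction protein Gja1 stood at 13.43 against 56.4 CPM, Hsd3b1 at 53.2 against 102 CPM and Cyp11a1, which starts steroid synthesis from cholesterol, at 9.001 against 25.9 CPM. Chromatin examples were the remodeller Chd1 (log2 fold -1.46) and the histone H3 methyltransferases Ehmt1 (-0.69) and Suv39h1 (-0.57). Another was Setd2, which methylates lysine 36 of the same histone and is needed for the oocyte methylome (254 CPM [249.8 to 259] against 358 CPM [353 to 363]; chromosome 9, 110532597 to 110618633). For the unfolded protein response they were the degradation ligase Syvn1 (-0.66), its partner Sel1l (-0.63), Edem1 (-0.55) and the cochaperone Dnajb11 (-0.49). Other higher genes were Vps33b of vesicle fusion (2.28), the calcineurin regulator Rcan1 (2.27) and the RNA-binding Pcbp3 (2.27). So were Dpy19l3 (2.22), the focal adhesion protein Lpp (59.5 against 12.9 CPM), Dcaf4 (2.0958) and Syt11 (1.89). Other lower genes were the lysosomal Psap (-2.4984), the dynein Dnah9 (-2.37) and the inositol transporter Slc2a13 (-2.36). So were Gclc, which limits glutathione synthesis (-2.25), Foxp2 (-2.23), Gstz1 (-2.21) and the arginine sensor Gatsl3 (-2.17). The other 15 lists lay inside.

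Pooled cumulus marker RNA was 367 CPM in F3 CD+DHT against 594 in its controls, where oocytes 19 and 21 lay above the fence. Without both, the cumulus median was -0.03 (percentile 26.03) and that of the unfolded protein response -0.05 (16.7). The cumulus list also came inside with the stricter oocyte filter (percentile 7.57) or a minimum of 20 CPM (4.72). Without control oocyte 21 alone the cumulus median was -0.14 (inside) and log2 folds were -1.67 for Psap, -3.21 for Vcan, -1.39 for Gja1 and 0.15 for Cyp11a1. Without control oocyte 19 they were -2.60 for Akr1c14 and -0.26 for Hsd3b1. Without CD+DHT oocyte 14 they were 1.66 for Vps33b, 1.30 for Rcan1 and 1.04 for Dpy19l3. Without oocyte 15 they were 1.05 for Pcbp3, 0.71 for Dcaf4 and 0.95 for Syt11. Folds moved away from 0 to -3.57 for Tmx3, -3.42 for Psap and -2.33 for Cyp11a1 without CD+DHT oocyte 14, -4.23 for Akr1c14 without oocyte 16 and -3.63 for Chst11 without oocyte 22. Without control oocyte 7 Pcbp3 was at 3.11 and without control oocyte 3 Dcaf4 was at 2.89. The chromatin list came inside without CD+DHT oocyte 13, 14 (-0.07), 16 or 22 or control oocyte 1, 2, 3, 6, 7, 9, 16 or 22. Its median was 0.11 with equal weights, 0.23 with oocyte medians and 0.11 with RPKM. The unfolded protein list came inside without CD+DHT oocyte 9 or 16 or control oocyte 2, 3, 5, 17, 19, 21 (-0.07) or 23. It also did with the stricter oocyte filter (27.57), a minimum of 1 CPM (7.12) or 20 CPM (6.5) or oocyte medians (6.19). The median over all genes was 0.03 for pooled counts and 0.14 for oocyte medians. With the latter the log2 folds of Chd1 (0.28), Ehmt1 (0.24), Syvn1 (0.89) and Sel1l (0.48) turned positive.

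The F3 comparison of HFHS+Veh with CD+Veh asked the same of the diet lineage. Its controls were the CD+Veh oocytes also set against F3 CD+DHT. They link what lay lower in both, such as the chromatin and unfolded protein lists, Akr1c14, Psap and Gatsl3. The inositol transporter Slc5a3 (23.9 CPM [20.5 to 27.6] against 2.94 CPM [2.52 to 3.41]; log2 fold 3.02; chromosome 16, 92058322 to 92087473) and the metalloreductase Steap4 (32.6 CPM [28.7 to 36.9] against 4.98 CPM [4.43 to 5.58]; 2.71; chromosome 5, 7960457 to 7982213) were highest relative to controls by the naming rule. Lowest by that rule were Serpinb9, an inhibitor of granzyme B (1.31 CPM [0.626 to 2.4002] against 30.0 CPM [28.6 to 31.4]; -4.52; chromosome 13, 33003250 to 33017957), and the lysosomal Psap (4.96 CPM [3.51 to 6.81] against 99.2 CPM [96.7 to 102]; -4.32; chromosome 10, 60277627 to 60302597). Next was Akr1c14 (10.8 against 93.2 CPM). DNA methylation and chromatin regulators lay lower (median log2 fold -0.24, percentile 0.13, 28 of 44). They were led by Ehmt1 (22.45 CPM [19.22 to 26.07] against 55.0 CPM [53.1 to 56.9]; -1.29; chromosome 2, 24789928 to 24919614) and the cofactor of oocyte DNA methylation Dnmt3l (15.9 CPM [13.22 to 19.01] against 32.2 CPM [30.8 to 33.7]; -1.02; chromosome 10, 78041947 to 78063622). Others were Kdm2b (-0.85) and Setd1a (-0.76). The unfolded protein response (median -0.39, percentile 0.425, 19 of 27 lower) and androgen and steroid genes (-0.29, percentile 1.38, 20 of 24 lower) were lower as well.

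In the unfolded protein response list of F3 HFHS+Veh the stress sensor Ern1 stood at 25.06 CPM [21.6 to 28.9] against 50.2 CPM [48.4 to 52.1] (chromosome 11, 106394650 to 106487852). The asparagine synthetase Asns stood at 25.19 against 61.7 CPM, the phosphatase subunit Ppp1r15b at 10.6 against 22.58 CPM and Edem1 at 60.6 against 113 CPM. Steroid genes were Akr1c18 (71.1 against 213 CPM), Cyp11a1 (9.66 against 25.9 CPM), the progesterone receptor membrane component Pgrmc1 (34.8 CPM [30.8 to 39.3] against 69.6 CPM [67.5 to 71.8]) and the glucocorticoid receptor Nr3c1 (18.9 against 35.0 CPM). Other higher genes were Mctp1 (log2 fold 1.94), the kinase Map3k4 (1.93), the kinetochore protein Zwilch (1.76) and Bank1 (1.69). So were Ralgapa1 (1.64), the olfactory receptor Olfr1164 (1.64), Nebl (1.56) and Cog5 of the Golgi (1.55). Other lower genes were Gatsl3 (-2.97), the motor Myo1e (-2.47) and the mucin glycosyltransferase Galnt6 (-2.37). So were Nelfcd, of transcriptional pausing (-2.22), the clock-linked repressor Bhlhe40 (-2.19), Wls, which carries Wnt proteins to the surface (-1.9564), and Sidt2 (-1.95). The other 15 lists lay inside.

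Pooled counts were lowest here, at 7662016 with no library above 1186699, and the characteristics of animal 22 named F2. Kept HFHS+Veh oocytes had a median of 7127 genes and 585662 counts, against 8226 genes and 2616474 counts in CD+Veh. Library quality was not parted from the lineage. Pooled cumulus marker RNA was 463 CPM in HFHS+Veh against 594 in controls. Without control oocytes 19 and 21 the steroid list (median -0.23, percentile 4.31) and the unfolded protein list (-0.19, 11.5) came inside and the chromatin list stayed outside (-0.22, 0.30). The chromatin list lay outside whichever single oocyte was left out but came inside without animal 22 (-0.11, percentile 7.98) or animal 26 (-0.16, 7.82), or with a minimum of 20 CPM (4.09) or RPKM (3.33). Its median was 0.03 with oocyte medians, with which Dnmt3l was at 0.38 and Akr1c18 at 1.40. The steroid list came inside without animal 22 (5.23), oocyte 2 (-0.22) or 8 of animal 22, oocyte 6 of animal 26, or control oocyte 4 or 21, or with a minimum of 20 CPM (3.985) or oocyte medians (11.37). The unfolded protein list came inside without animal 22 (-0.17, 13.08), animal 26 (2.78), oocyte 3 of animal 22, or control oocyte 21 or 23 (-0.24), or with a minimum of 1 CPM (15.21) or oocyte medians (11.475). Log2 folds were 0.23 for Nebl without oocyte 1 of animal 22, -3.61 for Serpinb9, -3.49 for Psap, -1.26 for Bhlhe40 and 0.25 for Cyp11a1 without control oocyte 21. That of Akr1c14 was -2.44 without control oocyte 19. Away from 0, oocytes of animal 22 left out gave -4.27 for Akr1c14 and -2.82 for Bhlhe40 (oocyte 1), -2.76 for Sidt2 and -2.04 for Asns (oocyte 3) and -4.58 for Cyp11a1 (oocyte 7), and oocyte 1 of animal 26 gave -3.25 for Nelfcd.

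**Figure D3:**
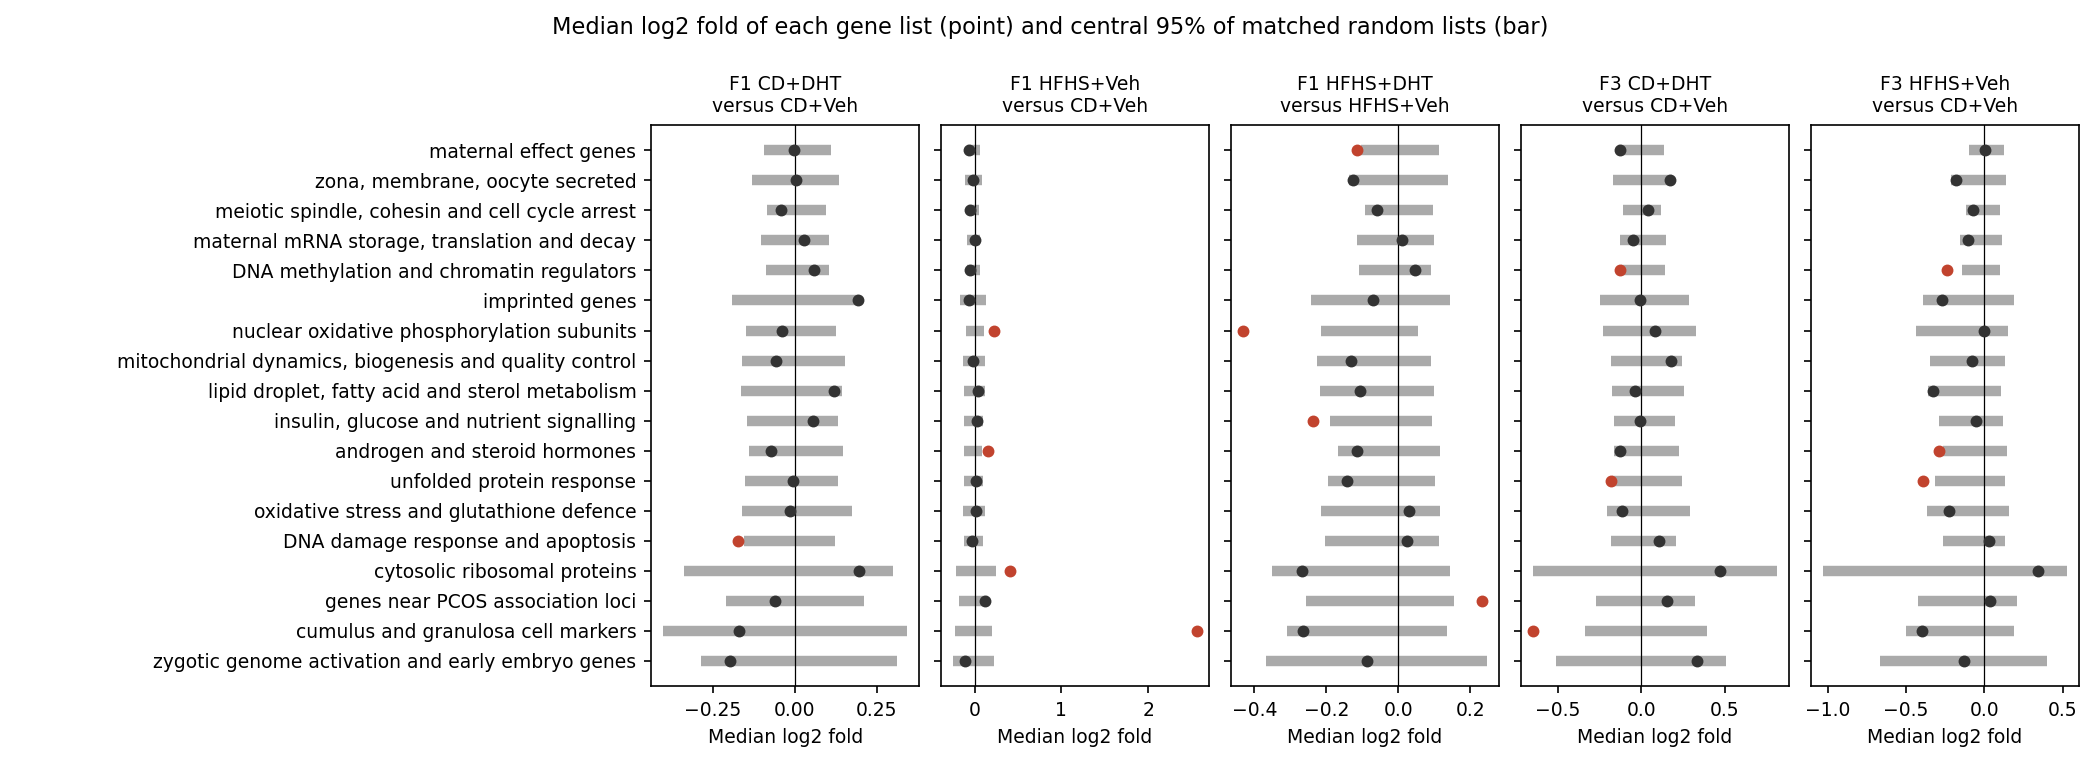
Median log2 fold of each of 18 gene lists in the 5 comparisons of F1 and F3. Points are list medians, red where they lie outside the grey bars, which span the central 95% of 10000 random lists matched on expression; cumulus markers in F1 HFHS+Veh reach 2.56.

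Across generations, no gene had passed the F2 edgeR threshold, so the rule for genes shared by the generations named none. Log2 folds of the CD+DHT lineage correlated across genes at Spearman rho = -0.115 between F1 and F2 (6990 genes), 0.0619 between F2 and F3 (6355) and -0.0095 between F1 and F3 (6324). For HFHS+Veh the values were 0.183 (7045 genes), -0.0056 (6226) and -0.104 (6232). Pairs of different lineages in different generations lay between -0.0642 and 0.0869. All were set against CD+Veh of their generation, so a trait of that lineage could link them. Genes are not independent replicates and these values carry no p. With equal weights of oocytes the F1 and F2 value of CD+DHT turned to 0.242 and the F1 and F3 value to 0.0831. For HFHS+Veh the F1 and F2 value was then 0.0714 and the F2 and F3 value -0.138. Pairs of different lineages lay between -0.0579 and 0.208 with these weights.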

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

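All tests named here were planned. In each F2 group of 4 or 5 animals, the highest and the lowest animal were compared with the others by the gap to the nearest animal as a share of the group's range. Of 72 groups of values examined, 4 held an animal that stood apart. Chance alone gives about 1 in 20 groups.

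Gjb6, the connexin gene lower in F2 CD+DHT by DESeq2 only, was at 0 in every CD+DHT animal except animal 7, whose single count gave a log2 CPM of -2.65. Tlr3, the receptor for double-stranded RNA, was at a log2 CPM of 5.55 in CD+DHT animal 8, far above the other 4 CD+DHT animals, so its mean in that group leans on 1 animal. Myo1a, named as higher in F2 HFHS+Veh, had a count in only 1 control animal, number 3, with a log2 CPM of -2.40. The summed cumulus and granulosa markers of HFHS+Veh animal 5 were 846 CPM, far above the other 3 animals of its group, and its oocyte 1 at 2197 CPM was the 1 F2 oocyte above the fence. No biological explanation was tested for these 4 values.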

How the results depend on the processing

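Leaving out single oocytes, oocytes high in cumulus markers, oocytes absent from the 2 normalised tables used and the animal number term were chosen after seeing the data; the other alternatives were planned. No paired analysis was possible because the F2 animal numbers are not shared between groups. Of 1963 values recomputed (single-oocyte omissions aside), 1414 counted as the same by the rule for their kind, 517 moved, 6 were weaker, 2 stronger and 24 reversed. An F2 gene counted as the same if its sign was kept and it did not pass, whatever its size. An F2 list did so if its camera direction was kept and it was still called. Of 1644 values for 174 named folds, 1629 kept their direction. Leaving out each F1 or F3 oocyte reversed 4 of 4230 gene values. These genes were named for their folds or small p-values in the same data, so most would keep their direction anyway. For the largest folds of F1 and F3 the rule already required oocyte medians to lie the same way. Mitochondrially encoded genes could not be left out (0 lines), the stricter filter left no F3 HFHS+Veh oocyte, and F1 and F2 HFHS+DHT are not in the 2 normalised tables used, so these gave no value. Pooled counts were lowest in F3 HFHS+Veh (7662016) and F1 CD+DHT (7900707). For the changes that follow, the cause was not tested.

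The count of F2 genes was 0 in 43 of 45 alternatives, each animal left out included (0 to 0 for both lineages), and 2 (CD+DHT) and 1 (HFHS+Veh) with DESeq2's Wald test. At an unadjusted p under 0.05, limma on animal means gave 663 and 234 genes and voom 533 and 169, with 0 called. Lists called for F2 HFHS+Veh were 0 with an estimated correlation and 0 with limma on animal means, and 0 to 3 with an animal left out (0 to 1 for CD+DHT). The correlation of the lineages was -0.111 with split controls.

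Lists outside the random range numbered, for F1 CD+DHT, 3 with equal weights, 3 with oocyte medians, 3 with RPKM and 1 to 3 with an oocyte left out. For F1 HFHS+Veh there were 8 with a minimum of 1 CPM, 1 without the cumulus-high oocyte and 1 to 7 with an oocyte left out. For F1 HFHS+DHT there were 7 with equal weights and 1 to 7 with an oocyte left out. For F3 CD+DHT there were 6 with equal weights, 6 with RPKM, 1 with a minimum of 20 CPM and 1 to 5 with an oocyte left out. For F3 HFHS+Veh there were 6 with equal weights and 1 to 6 with an oocyte or animal left out.

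Medians that reversed were oxidative phosphorylation in F1 HFHS+Veh (-0.0414 with a minimum of 20 CPM), steroid genes there (-0.02 with oocyte medians) and maternal effect genes in F1 HFHS+DHT (-0.197 to 0.0037 with an oocyte left out). So did those of chromatin regulators in F3 CD+DHT (0.109 with equal weights, 0.228 with oocyte medians, 0.105 with RPKM) and in F3 HFHS+Veh (0.0338 with oocyte medians). With oocyte medians the log2 folds of Bcl2l1 (0.383) in F1 CD+DHT and Gata4 (-0.0895) in F1 HFHS+DHT reversed. So did Chd1 (0.284), Ehmt1 (0.245), Syvn1 (0.888; 0.146 with RPKM), Sel1l (0.477) and Cyp11a1 (1.78) in F3 CD+DHT, and Dnmt3l (0.376) and Akr1c18 (1.40) in F3 HFHS+Veh. Cyp11a1 in F3 CD+DHT also reversed with the stricter filter (0.761) and with the oocytes of those tables or without cumulus-high oocytes (0.102), and in F3 HFHS+Veh with either of the last (0.204). With an oocyte or animal left out, Bcl2l1 ran from -0.589 to 0.0987, Cyp11a1 from -2.33 to 0.152 in F3 CD+DHT and from -4.58 to 0.253 in F3 HFHS+Veh.

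Between generations rho became 0.242 with equal weights and -0.151 with a minimum of 20 CPM for CD+DHT F1 and F2, 0.0187 for F2 and F3 and 0.0831 for F1 and F3 with equal weights. For HFHS+Veh, with equal weights and a minimum of 20 CPM, it became 0.0714 and 0.311 for F1 and F2, and -0.138 and -0.0453 for F2 and F3. Pairs of different lineages reached 0.208 with equal weights and 0.192 with the minimum of 20 CPM, both for HFHS+Veh F1 with CD+DHT F2.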

Other observations

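Chosen only after the result was seen were the genes of the first component and of the 3 generations, the tests of 1 library, of depth for the first component and of the generation labels. The other tests were planned. Genes that lay furthest along the first principal component of F2 animals were of 2 kinds. On the positive side were transcripts abundant in all animals. They were Wtap, Paip1, a stimulator of translation (1821 CPM in animal 3, 38860.0 in animal 9), the Notch ligand Jag1 (2056 to 29830.0 CPM) and the sterol sensor Insig1 (944 to 15960.0 CPM). On the negative side were Nupr1, Prr5, a subunit of mTOR complex 2 (0 to 30.4 CPM), the leukocyte antigen Cd52 (0 to 25.67), and genes of steroidogenic follicle cells. The latter were Ephx2 (0 to 167), Akr1c18 (0 to 60.5), Gja1 (0 to 81.1, highest in animal 9 at the positive end) and Hsd3b1 (0 to 70.2). By list, cumulus markers (19 of 23 members negative, percentile 0) and zona pellucida and secreted factors (17 of 22, percentile 0) loaded on the negative side beyond random lists. So did lipid metabolism (39 of 48, percentile 0.22), maternal effect genes (22 of 38, percentile 0.59), blood, immune and stromal markers (5 of 6, percentile 1.37) and insulin and glucose genes (35 of 47, percentile 1.88).

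Some genes were picked, after the values were seen, for lying on the same side in all 3 generations of a lineage by pooled counts, and chance alone puts a share of all genes there. How many genes chance would give was not counted, so they are no evidence of a shared pattern. In CD+DHT they included Nobox, a transcription factor of oocyte growth (log2 folds -0.89, -0.60 and -1.37 in F1, F2 and F3; chromosome 6, 43303674 to 43309554), Pdss2, of coenzyme Q synthesis (-0.52, -0.63 and -0.59), and the protease Blmh (-0.67, -0.51 and -1.01). The chaperone Hspa4 (-1.12, -1.10 and -0.50; chromosome 11, 53259814 to 53300457) did not keep its side in F3 by oocyte medians, which were 18.96 CPM in CD+DHT and 7.15 CPM in CD+Veh. In HFHS+Veh they included Hspa4 (-0.87, -1.04 and -1.75), Tdrd5, of germline small RNA pathways (-0.63, -0.62 and -0.82), and, higher, the lipid enzymes Acly (0.28, 0.36 and 0.46) and Acsl3 (0.33, 0.29 and 0.39). Dnmt3l (-0.63, -0.96 and -1.02) turned to 0.38 in F3 with oocyte medians. Both lineages share their controls within each generation, which links Hspa4 in both.

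F1 HFHS+Veh oocytes held more cumulus and granulosa RNA than F1 CD+Veh oocytes, at a pooled 602 against 239 CPM over the 34 markers. The median log2 fold of the 14 members measured, some of which entered only through high HFHS+Veh levels, was larger at 2.56. A single library was not the whole of it, as the median stayed at 1.85 without oocyte 1, and neither was depth, as thinning every oocyte to 158259 counts left 1.68. RNA of cumulus cells carried along with the oocytes is a candidate explanation. A profile was taken from F3 CD+Veh oocyte 21, markers left out. It held the 100 genes most in excess there among those with a mean of at least 5 CPM over F1 HFHS+Veh and CD+Veh. Their median was 0.66 in F1 HFHS+Veh against its controls, above the 0.12 that bounds random lists, with 82 of 100 higher. Genes low in CD+Veh could enter only through high HFHS+Veh levels, which favours a positive median, so this value cannot decide. That profile came from 1 oocyte, and its median was also 0.26 in F1 CD+DHT, where 3 of 8 cumulus markers were higher (Tnfaip6 at 16.45 against 2.13 CPM) and their median was -0.17, so how specific it is was not settled. The explanation stays open, and so does whether the diet, the hormone named in the conflicting labels or the handling of the oocytes set the amount, as the design does not part them.

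F2 animals spread along a first principal component that did not follow their groups. Depth may be set aside as the whole cause, since the component after thinning every animal to 9933410 counts correlated with the original at 0.989. The same holds for a few dominant genes (0.962 without the 100 with the most counts, which took 24.3% to 41.3% of an animal's counts). For carried cumulus RNA the correlation was 0.982 over the 9475 genes not in excess in F3 CD+Veh oocyte 21, but this cannot decide. Those were most of the 11963 genes tested, and that oocyte held 4603 genes, so follicle cell genes absent from it stayed in. Cumulus markers loaded on the negative side beyond random lists, and carried cumulus RNA stays open. Animals 8, 9 and 10, at the positive end, had the lowest median numbers of genes per oocyte (7957, 7771 and 8448), and after thinning 10298, 10363 and 10518 genes against 11460 to 11820 in the 8 animals below 0. The quality of the RNA or libraries was not tested and stays open, batches of collection are not in the labels, and no biological explanation was tested. With the animal number as a linear term 0 genes passed for it by edgeR and 922 had an unadjusted p under 0.05.

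Titles and characteristics disagreed on the generation of 16 HFHS+Veh oocytes. Of the 8 titled F2 but labelled F3, 8 of 8 had a spike-in share nearer the F2 median (0.109%) than the F3 median (0.336%). They came only from animals 10 and 5, so they are not independent. Shares of oocytes without a conflict overlapped, from 0.028% to 3.46% in F2 and from 0.117% to 14.33% in F3. Even if the share reflects handling, this leans toward F2 but cannot settle it. For the 5 kept oocytes titled F3 but labelled F2, 4 lay nearer the F3 median, so these cannot be told apart at that number.

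The real count of genes called by edgeR in F2 was 0 for both lineages, so every split of the animals gave as many by construction (100 of 100 drawn for CD+DHT, 35 of 35 for HFHS+Veh), and whether chance can be excluded was not tested by them. Nearly all splits called 0 genes. Above 0 were 2 of the 100, with a highest of 66 for animals 2, 3, 6, 7 and 17 against 8, 9, 13 and 14. Above 0 was 1 of the 35, with 189 for animals 10, 13, 14 and 19 against 2, 3, 4 and 5. These highest splits point to a structure of the samples, as both set animals along the first principal component and not by group.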
